A study of Arabidopsis thaliana with 2 samples.

How the data were processed

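Whole-genome bisulfite sequencing was analysed for 6 libraries, 3 biological replicates of systemic leaves under each of 2 labels, control and Dox. Genomic DNA was extracted from leaves and treated with bisulfite, per the labels' protocols. Per the submitters' processing notes, Bismark 0.12.5 and Bowtie2 were used; their settings and the genome build are not given in the sources used here. The deposited tables list every cytosine with its strand, context and trinucleotide and with 2 read counts, methylated and unmethylated, as raw counts that were not normalized. All 6 tables listed the same 43080083 cytosines. No step that removes duplicate reads or unconverted reads is named in the sources used here, so reads may not be independent molecules and intervals cover counting error only.

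Group membership came from the sample labels. The tables of the control sample carry names that read as Dox-treated local tissue; the labels were followed, and the names were not used to assign any library. If the names rather than the labels are right, the comparison is between local and systemic tissue of Dox-treated plants. Replicate numbers are the order of the tables and come from no label.

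A level is methylated reads over all reads of a context, from both strands. Nuclear, chloroplast and mitochondrial cytosines were kept apart. The chloroplast level of the same library and context gave the background. Levels were compared with exact two-sided permutation tests of 3 against 3, whose smallest p is 0.1, with Benjamini-Hochberg adjustment over 3 contexts or 19 regional values. Single levels have 95% Wilson intervals; that of the CG level of control replicate 1 is 28.27% to 28.29%.

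Windows of 100 bp tiled the 5 nuclear chromosomes. A window entered a context with at least 3 cytosines and 10 reads in every library, and a gene body or gene flank with at least 50 reads. Methylated and unmethylated counts were tested with a quasi-binomial logistic model, with group as the only term. The Pearson dispersion on 4 residual degrees of freedom was moderated with limma 3.58.1 (squeezeVar, trend on log reads) and never let fall below 1. The trend carried 123 prior degrees of freedom in CG windows and 53.0 in CHH, against the 4 of a window's own replicates. In CHG windows it carried infinitely many, so a window's own spread did not enter its p. F test p values, or chi-square p values where the prior was infinite, were adjusted by Benjamini-Hochberg within a context. A window was called at an adjusted p below 0.05 and an absolute difference of at least 40 (CG), 20 (CHG) or 10 (CHH) percentage points. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16. Median depth was 70 reads per window and library in CG and CHG and 285 in CHH.

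Genes came from a table of assembly TAIR10.1 with 37899 nuclear genes, 27444 protein coding and 4843 pseudogenes. The tables name no build, so its coordinates are not printed and it was checked against the listed cytosines: of 625 tRNA genes, 441 showed the conserved B box motif in place, against 270 when shifted by 50 bp and 5 when shifted by 100 bp. The table gives no strand and no transposable elements. Promoters as planned were therefore not tested and the 1 kb flanks on both sides of a gene were summed, a choice made after the data were seen; transposable elements were not analysed here, and the pseudogene class is described without calling its members transposons. Pericentromeres are the 51 of 240 bins of 500 kb in which coding genes cover under 40% of bases. Gene lists held 136 entries in 8 lists and were tested with Fisher's exact test for having a called window in the gene or its 1 kb flanks. One entry of the list of methylation-controlled loci was entered in place of another gene and kept as written.

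Named regions and genes followed a rule written before the data were examined. Called windows of one context and direction that were adjacent or 1 window apart were merged, and per context and direction the 4 regions with the most windows, ties by absolute difference, whose libraries did not overlap were named with their overlapping or nearest gene. Also named were list members with a called window or an adjusted p below 0.05 over all genes, 9 genes whatever their value, and the window of smallest p where nothing was called. The design, tests and most alternatives were also written before the data were examined.

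The model was tested on simulated counts with the real read totals and levels, scored at an adjusted p below 0.05 without the minimum difference. In CHH windows it recovered 73 of 100 differences of 10 points and 97 of 100 of 20 points, with 4 false calls among 1170900; in CHG windows 43 of 100 of 20 points and 99 of 100 of 40 points, with 5 false calls; in CG windows 100 of 100 of 40 points, with 13 false calls. edgeR's quasi-likelihood test on the same simulated CHH windows recovered 7 of 100 and 41 of 100, fewer than the model. In the real data edgeR called 0. The simulation cannot say why, because its spread between replicates was set and not taken from the data. Gene body differences of 10 CG points were recovered in 97 of 100, of 10 CHG points in 82 and of 5 CHH points in 94, but of 5 CHG points in 27 and of 2 CHH points in 33. False calls among gene bodies were 12 in CG, 4 in CHG and 6 in CHH. In raised windows the median estimates were 9.71 points for 10 in CHH, 20.4 for 20 in CHG and 40.4 for 40 in CG. These lie near the minimum differences, so the full window rule would recover fewer.

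Alternatives were other read minimums, cytosines with at least 4 reads, no minimum difference, windows of 200 bp, Fisher's exact test on pooled reads, edgeR, leaving out windows of over 5 times the median depth, the replicate number as a block, background-corrected levels, and leaving out each library in turn. All 10 splits of the 6 libraries into 3 and 3 were also tested.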

Results

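Whole-genome bisulfite sequencing measured cytosine methylation in leaves of Arabidopsis thaliana. In this assay bisulfite turns unmethylated cytosines into uracil, so that a cytosine still read as C was methylated. The series addresses systemic acquired adaptation to mitochondrial stress: leaf tissue was treated locally and untreated, systemic leaves were sampled. The labels give 2 groups of 3 biological replicates each, systemic leaves of plants whose local tissue received water (control) and systemic leaves of plants whose local tissue received Dox at 25 in the labels' unit of um/g (Dox). The labels do not expand the name Dox. The tables deposited under the control label carry names that read as Dox-treated local tissue, while the title and treatment field of that sample read as water. The groups follow the labels here, and every comparison below is between the libraries deposited under the control label and those deposited under the Dox label. Replicate numbers are the order of the tables only. The tables list the same 43080083 cytosines, of which 42124942 to 42290082 had a read in a library, and mean nuclear depth per cytosine was 11.7, 11.3 and 12.5 reads in the control libraries and 13.0, 13.2 and 9.10 reads in the Dox libraries.

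The first comparison asked whether the methylation level of the nuclear genome differed between the systemic leaves of the groups. Neither CG, CHG nor CHH methylation (H is A, C or T) differed by more than the spread between replicates. The CG level was 26.9% ± 1.23 (SD, n = 3) in the control and 25.9% ± 0.819 in the Dox libraries (exact two-sided permutation p = 0.5, the smallest possible being 0.1). CHG methylation, the mark of heterochromatin maintained through histone H3 methylation, was 7.43% ± 0.768 and 7.10% ± 0.195 (exact p = 0.8). CHH methylation, which depends mostly on small RNAs and chromomethylases, was 2.41% ± 0.342 and 2.33% ± 0.0304 (exact p = 1). Control replicate 1 lay above the other 5 libraries in each context, at 28.3%, 8.31% and 2.80%; without it the CHG and CHH differences turned from lower to higher in Dox, by 0.116 and 0.112 percentage points (exact permutation p = 0.4 and 0.1), and the CG difference went from -0.968 to -0.265 points. The chloroplast genome, which is unmethylated and so gives the background of non-conversion and sequencing error, read 0.622% ± 0.0272 in control and 0.649% ± 0.0152 in Dox for CG (exact p = 0.3).

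By part of the genome, pericentromeres and the pseudogene class of the gene table carried the highest levels and coding gene bodies carried CG methylation almost alone. Pericentromeric CG methylation was 63.0% ± 2.52 in control and 61.2% ± 1.07 in Dox, against 15.4% ± 0.461 and 15% ± 0.406 in the chromosome arms. Control replicate 1 alone read 65.8% in pericentromeres, and the other libraries of both groups 59.9% to 62.3%. Coding gene bodies read 16.5% ± 0.436 and 16.2% ± 0.372 in CG, but 0.937% ± 0.0759 and 0.947% ± 0.0226 in CHH, close to the chloroplast background of 0.711% ± 0.0340 and 0.741% ± 0.0249. Pseudogenes read 76.3% ± 1.55 and 75.5% ± 0.782 in CG, 34.2% ± 2.29 and 34.3% ± 0.895 in CHG, and 7.59% ± 1.05 and 7.35% ± 0.284 in CHH. Among trinucleotides, CAA and CTA, the preferred CHH sites of chromomethylase 2, read 4.61% ± 0.629 and 4.42% ± 0.0670, against 1.52% ± 0.209 and 1.5% ± 0.0320 at the other CHH sites. None of the 19 regional comparisons passed (exact permutation tests, Benjamini-Hochberg adjusted p = 1 in each), and none could, since 3 libraries against 3 cannot go below 0.1.

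**Figure D1:**
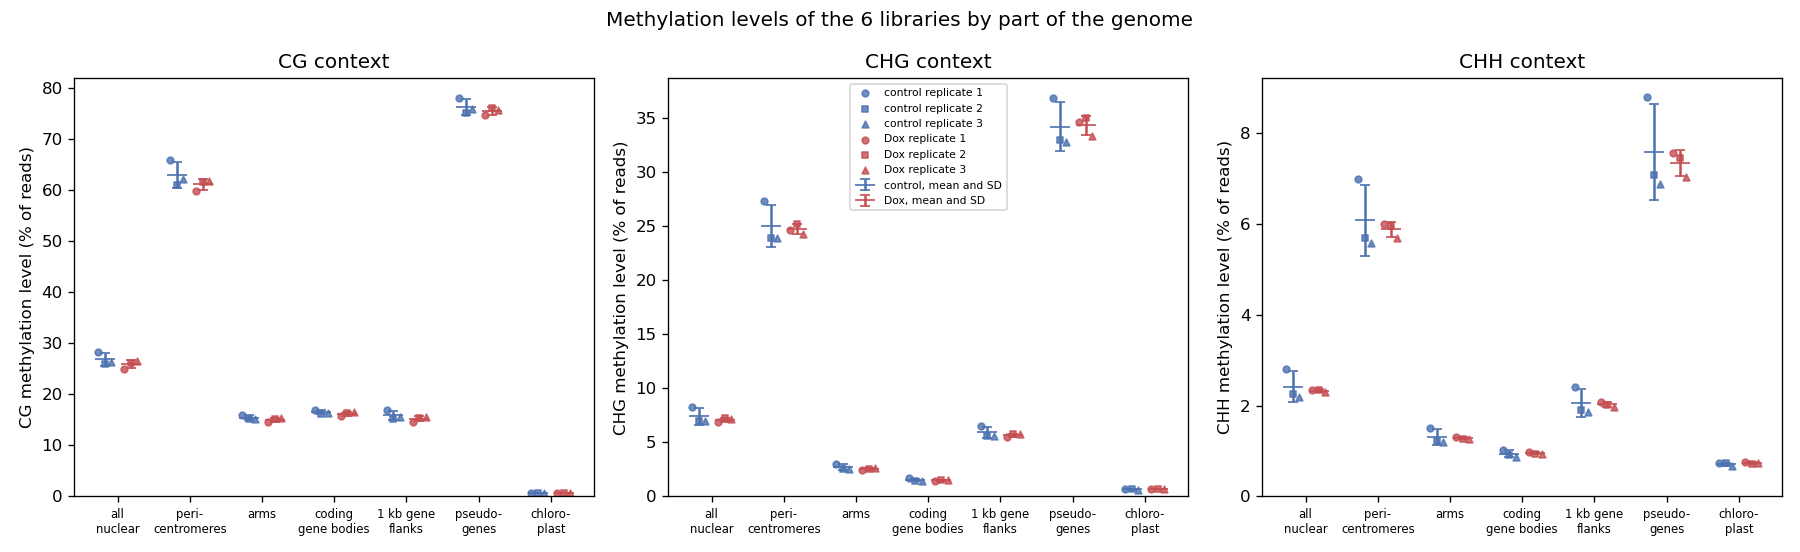
Methylation level (vertical axis, % of reads) of each of the 6 libraries in CG, CHG and CHH, by part of the genome; points are libraries, bars the mean and SD of 3. Control replicate 1 lies above the other libraries in the nuclear genome as a whole (28.3% in CG), and the chloroplast stays below 1% in every context.

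Windows of 100 bp were then tested for local differences. CHH methylation gave nearly all of the calls: 125 windows were higher and 35 lower in Dox, out of 1170900 tested. Of the 10 splits of the 6 libraries into 3 and 3, 6 called at least as many, the labelled split among them. The highest other split called 1724, so the count is not above what other groupings of these libraries gave. Median levels of the higher windows were 16.8% in control and 34.2% in Dox, and those of the lower windows were 38.2% and 17.3%. In CHG 2 windows were higher and 1 lower out of 819958, and in CG no window out of 688136 passed both the adjusted p and the difference of 40 points, with 43789 at an unadjusted p under 0.05. The libraries of the groups did not overlap in 111 of the 125 higher and 32 of the 35 lower CHH windows. The calling rule favours such windows, so these counts are no separate support for the calls. Of all tested CHH windows 9.59% were without overlap, where chance gives 10%. The CHH calls depended on the method and on single libraries. edgeR's quasi-likelihood test on the same counts called 0 windows in CG, CHG and CHH (56782 of the 1170900 CHH windows at an unadjusted p under 0.05). Windows of 200 bp gave 0 higher and 1 lower, and leaving out control replicate 1 gave 862 higher and 71 lower. Counts of higher and lower windows were 73 and 69 without control replicate 2, 81 and 121 without control replicate 3, 76 and 49 without Dox replicate 1, 57 and 19 without Dox replicate 2, and 95 and 15 without Dox replicate 3.

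The CHH window with the smallest adjusted p lay beside a gene of the methylation machinery itself. It was in the 1 kb flank of NRPD2A (AT3G23780), the subunit shared by RNA polymerases IV and V of RNA-directed DNA methylation, on chromosome 3 from 8574601 to 8574700. Positions are those of the deposited tables, whose genome build is not given in the sources used here. CHH methylation there was 36.7% ± 6.08 in control and 61.3% ± 0.976 in Dox (SD, n = 3), from 230 to 387 reads per library (adjusted p = 7.57e-06, moderated with limma). It passed in all 6 fits that left out one library, and edgeR did not call it. The flank of ALD1 (AT2G13810), the aminotransferase of pipecolic acid synthesis needed for systemic acquired resistance, held a CHH window on chromosome 2 from 5773001 to 5773100 with 11.2% ± 7.98 in control and 28.1% ± 1.43 in Dox (159 to 381 reads, adjusted p = 0.00881). It passed in 2 of the 6 leave-one-out fits.

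Of the 4 CHH regions lower in Dox named by the fixed rule, 3 lay over 1 kb from the nearest gene. On chromosome 2 from 6738401 to 6738600, in a pericentromeric stretch whose nearest gene is NRPB3, a subunit of RNA polymerase II, CHH methylation was 49.9% ± 7.59 in control and 22.3% ± 4.77 in Dox (238 to 696 reads, adjusted p = 9.41e-05). On chromosome 1 from 9708201 to 9708300, within 1 kb of AT1G27880, it was 67.5% ± 9.09 and 35.4% ± 18.3. These 2 regions passed in all 6 leave-one-out fits. On chromosome 2 from 1803501 to 1803600 (nearest gene the pseudogene AT2G05080) the levels were 52.6% ± 9.08 and 27.3% ± 13.1, and on chromosome 3 from 15733101 to 15733200 (nearest gene AT3G43870) 48.8% ± 27.9 and 23.9% ± 2.83. The region near AT2G05080 passed in 5 of the 6 leave-one-out fits. The region near AT3G43870 passed in 2, and without control replicate 1 its pooled difference was -9.24 points instead of -32.5.

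Of the CHH regions higher in Dox, the 4 named by the fixed rule were all pericentromeric. Beside the pseudogene AT5G35420, chromosome 5 from 13656501 to 13656700 read 31.0% ± 3.09 in control and 47.3% ± 7.03 in Dox from 507 to 749 reads. Beside the pseudogene AT5G33303, chromosome 5 from 12569101 to 12569300 read 16.4% ± 3.5 and 30.5% ± 7.43. Near the transcribed pseudogene AT4G07747, chromosome 4 from 4547901 to 4548000 read 25.2% ± 18.9 and 69.4% ± 27.1. Near AT2G07440, chromosome 2 from 3092801 to 3093000 had no methylated read in control, 0 of 272 reads, and 21.2% ± 12.7 in Dox. If pooled and independent, the 272 reads allow a control level of up to 1.1%, a limit that leaves out the spread between libraries. These 4 regions passed in 1 or 2 of the 6 leave-one-out fits.

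In CHG the 3 called windows were pericentromeric too. Within the pseudogene AT1G37060 (chromosome 1, 14084601 to 14084700) CHG methylation was 36.1% ± 10.6 in control and 61.8% ± 11.6 in Dox; beside the pseudogene AT5G28696 (chromosome 5, 10737901 to 10738000) it was 10.3% ± 3.93 and 30.3% ± 15. Beside AT4G04601 (chromosome 4, 2308401 to 2308500) it was 42.7% ± 1.62 and 22.2% ± 1.81. Simulated data gave 5 false calls among as many CHG windows at an adjusted p below 0.05 alone. Those data held planted differences, of which 43 of 100 of 20 points and 99 of 100 of 40 points were recovered. The recovered windows loosen the p cutoff, so the 5 do not give the number of false calls to expect among the 3 called here. None of the 3 passed in a leave-one-out fit, under the replicate block or with edgeR. In CG the window with the smallest p in each direction was not called: its adjusted p was below 0.05, but its pooled levels differed by less than 40 points. Neither window had an adjusted p below 0.05 with edgeR, under the replicate block or in any of the 6 leave-one-out fits. Over AT2G03865, a gene of the miscellaneous RNA class near the end of chromosome 2 (7201 to 7300), the level was 85.2% ± 10.3 in control and 48.8% ± 8.24 in Dox, and within 1 kb of AT3G62050 on chromosome 3 (22977901 to 22978000) it was 11.6% ± 3.93 and 40.5% ± 17.8.

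**Figure D2:**
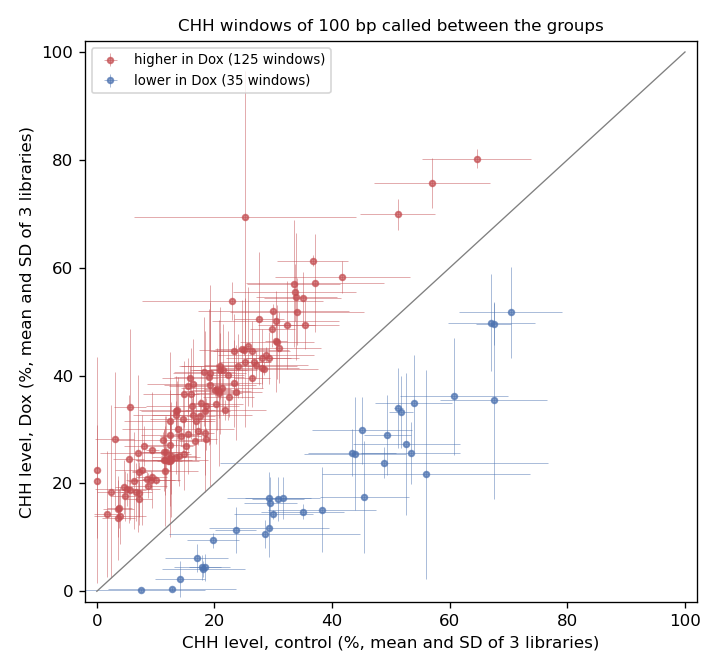
CHH level of the 160 called windows in control (horizontal axis, %) against Dox (vertical axis, %); each point is the mean of 3 libraries with its SD in both directions, and the grey line marks equal levels. The 125 windows above the line were higher and the 35 below it lower in Dox, with medians of 34.2% and 17.3% in Dox.

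Called CHH windows were enriched in the flanks of coding genes. Of the 160, 38.8% lay in the 1 kb flanks of coding genes, against 19.2% of tested windows (odds ratio 2.67, Fisher's exact p = 8.44e-09), and 8.75% in coding gene bodies, against 56.5% (odds ratio 0.0737, Fisher's exact p = 2.75e-37). Pericentromeres held 40% of the calls and 20.6% of tested windows (odds ratio 2.56, Fisher's exact p = 2.28e-08), and pseudogenes 5.63% and 8.96% (odds ratio 0.605, Fisher's exact p = 0.165). The flank enrichment was also seen against windows with a level of at least 5%, with an odds ratio of 3.87. Against that background the other classes did not keep their direction or size: the odds ratio was 1.25 for coding gene bodies, 0.227 for pericentromeres and 0.0821 for pseudogenes. Neighbouring windows are not independent, so these p values only describe the windows. Whether the calls of other splits of the libraries gather in flanks too was not tested, so the enrichment is not tied to the Dox label.

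No gene body and no pair of 1 kb gene flanks passed in CG, CHG or CHH. Gene bodies were tested for 36502 genes in CG, 36508 in CHG and 37508 in CHH. An unadjusted p under 0.05 was found for 2033, 1438 and 1327 of them, or 5.57%, 3.94% and 3.54%, where chance gives 5%. For flanks it was found for 2264 of 37599 genes in CG (6.02%), 1765 of 37589 in CHG (4.70%) and 1184 of 37649 in CHH (3.14%). The smallest adjusted p was 0.441 for gene bodies and 0.208 for flanks (limma-moderated quasi-binomial model). edgeR also called 0. In simulated data edgeR recovered 75 of 100 gene bodies changed by 10 CG points, where the model used here recovered 97. It recovered 0 of 100 changed by 10 CHG points and 4 of 100 changed by 5 CHH points, where the model recovered 82 and 94. The spread between simulated replicates was set and not taken from the data. These rates therefore do not say why edgeR called 0 in the real data. Differences were small: 95% of gene bodies differed by less than 2.83 points in CG, 2.03 in CHG and 0.740 in CHH. Without control replicate 1, 36 gene bodies were called higher in Dox in CHG, 35 of them pseudogenes.

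Genes of the lists fixed in advance rarely had a called window. Of the DNA methylation machinery 1 of 32 genes had one (NRPD2A), and of the systemic resistance and salicylic acid genes 1 of 19 (ALD1), against 0.391% and 0.390% of other genes (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.474 for both). With flanks of 2 kb, 2 of the 32 machinery genes had one, NRPD2A and the histone methyltransferase gene SUVH4 (AT5G13960), the latter named after its values were seen (Fisher's exact test, adjusted p = 0.148). No member had one among the 14 loci controlled by DNA methylation, the 20 genes of the mitochondrial stress response, the 12 of mitochondrial proteostasis and genome maintenance, the 7 of chloroplast retrograde signalling, the 17 of systemic ROS and wound signalling and the 15 photosynthesis genes kept for comparison (adjusted p = 1 each). Over all genes, no member's gene body or flanks passed. In gene body CG methylation, 14 of the 32 machinery genes were above and 18 below their control level, with medians of 25.4% in control and 24.9% in Dox. In flank CG methylation, 13 of the 20 mitochondrial stress response genes were above and 7 below, with medians of 10.2% and 9.93%, and 5 of the 14 loci controlled by DNA methylation were above and 9 below, with medians of 10.7% and 8.41%.

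Adjusted over the list alone, 6 of the members' values passed, and these are named after their values were seen. In the mitochondrial stress response, flank CG methylation was lower in Dox at NDB4, an alternative NAD(P)H dehydrogenase (17.5% ± 0.535 in control, 13.0% ± 0.445 in Dox, adjusted p = 0.00655 over the list alone and 0.537 over all genes). It was also lower at AOX1D, an alternative oxidase (40.1% ± 2.72 and 33.0% ± 2.66, adjusted p = 0.0352 over the list and 0.638 over all genes). RECA3, which maintains the mitochondrial genome, had a gene body CG level of 27.0% ± 2.09 in control and 32.9% ± 2.69 in Dox (adjusted p = 0.0296 over the list and 0.826 over all genes). The photosynthesis comparison list gave as many: LHCB5 in CG (6.34% ± 0.104 and 9.70% ± 0.770) and LHCA2 in CG (37.4% ± 3.3 and 43.4% ± 2.57) and CHG (6.01% ± 0.0291 and 8.25% ± 0.194). These came from 48 combinations of list, region and context.

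The 9 genes named whatever their value did not pass in any context. At SDC, a gene silenced by flanking tandem repeats, flank CG methylation was 41.6% ± 4.51 in control and 34.3% ± 1.31 in Dox and flank CHG 19.3% ± 3.43 and 14.5% ± 2.32 (adjusted p = 0.644 and 0.945). At FWA, a silenced flowering gene, flank CG was 32% ± 2.94 and 27.7% ± 1.54. ROS1, the DNA demethylase, had 28.8% ± 2.01 and 27.4% ± 2.63 in its gene body. IBM1, a histone demethylase that keeps CHG methylation out of genes, had 36.5% ± 1.91 and 36.7% ± 0.980 in CG and 4.24% ± 0.471 and 3.52% ± 0.277 in CHG. QQS, an orphan gene with a methylated surrounding, had flank CG levels of 70.9% ± 1.13 and 72.1% ± 3.31. AOX1A, the stress-induced alternative oxidase, was unmethylated in its body (0.603% ± 0.36 and 0.701% ± 0.0899) with flanks at 38.3% ± 1.41 and 40.8% ± 3.53. ANAC017, the transcription factor of mitochondrial retrograde signalling, had gene body CG levels of 15.4% ± 1.26 and 14.6% ± 0.731. MSH1, which guards organelle genomes, had 60.9% ± 2.09 and 59.6% ± 1.01. PR1, the marker of salicylic acid responses, stayed near the chloroplast background (0.859% ± 0.291 and 0.767% ± 0.302).

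**Figure D3:**
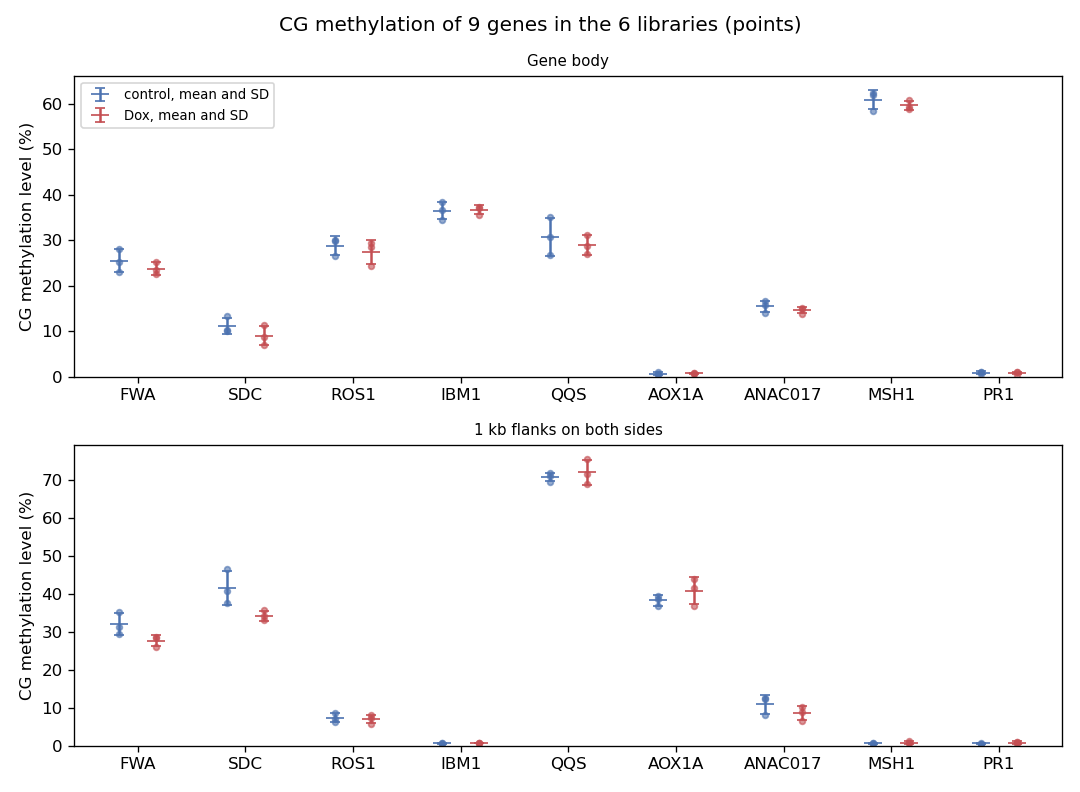
CG methylation level (vertical axis, %) of 9 genes in gene bodies and in the 1 kb flanks on both sides; points are the 6 libraries, bars the mean and SD of 3. The group means lie farthest apart in the SDC flanks (41.6% in control and 34.3% in Dox).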

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

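The tests of the mitochondrial contig were chosen after its values were seen. Reads on the mitochondrial contig, which the comparisons do not use, carried apparent methylation above the chloroplast background in every library. The contig's level ranged from 4.33% to 9.25% in CG, from 2.07% to 4.17% in CHG and from 1.01% to 1.57% in CHH, while the chloroplast stayed at or below 0.768% in all 3 contexts. Incomplete conversion would raise the contexts alike, but the lowest ratio of CG to CHH level on the contig was 4.18, against at most 0.883 on the chloroplast, which argues against it. A candidate explanation is reads from nuclear copies of mitochondrial DNA, which are methylated and would be placed on the contig: the methylated CG reads of the contig per 1000 nuclear CG reads varied by a CV of 5.45% between libraries, against 28.7% for the contig's CG level. No biological explanation was tested, and methylation of mitochondrial DNA itself stays open.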

How the results depend on the processing

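The use of both gene flanks, for flanks and for gene lists, and of edgeR on gene bodies and flanks was chosen after the data were seen; the other alternatives were planned. Promoters and transposable elements were not run. Of the 90 alternative counts of windows, 49 stayed within 1.5 times the reported count and 41 did not; the cause was not tested except where fewer libraries are the construction. Windows of 200 bp called 1 higher and 0 lower in CHG and 0 higher and 1 lower in CHH. edgeR called 0 in every context, and Fisher's exact test on pooled reads called 0 higher and 1 lower in CG, 3 higher and 4 lower in CHG, and 905 higher and 400 lower in CHH. With no minimum difference, 1 CG window was higher and 4 lower, and 152 CHH windows were higher and 55 lower. With the replicate number as a block, 0 CHG windows were called in either direction, and in CHH 190 higher and 65 lower. The replicate numbers are not shown to pair the libraries: deviations of same-numbered libraries correlated between -0.617 and 0.754, and 2, 3 and 4 of the 6 libraries were closest to their own number in CG, CHG and CHH. Leaving out each library gave 0 CHG windows in either direction, 57 to 862 higher and 15 to 121 lower in CHH, the 862 without control replicate 1 and the 121 without control replicate 3. Of the 160 CHH windows, 10 were called in all 6 of these fits, and all 160 kept their direction. In gene bodies CHG the range was 0 to 36 higher and in flanks 0 to 1, the highest without control replicate 1; all other gene body and flank counts stayed at 0. Over named windows, 127 alternatives left the call as it was and 61 ended it, with no change of direction. The 127 include those of the CG windows named though not called, where there was no call to end. The odds ratio of CHH calls against windows with a level of at least 5% was 1.25 in coding gene bodies, 0.227 in pericentromeres and 0.0821 in pseudogenes. No gene list passed under any alternative.

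No level difference passed under any setting, which the design does not allow, so the p values say nothing about stability. Without control replicate 1, CHH levels were higher in all 3 Dox than in both control libraries genome-wide (2.21% ± 0.0432 and 2.33% ± 0.0304 in control and Dox), in arms, coding gene bodies and flanks and at other CHH sites (exact permutation p = 0.1 each, the smallest possible). The chloroplast CHH background was then also higher in Dox on average, by 0.041 points, against 0.0523 in coding gene bodies. As the mean over cytosines with at least 4 reads, the Dox minus control difference was -0.113 points for genome-wide CG and turned positive for genome-wide CHG (0.00615 points), pericentromeres in CG (0.12) and CHG (0.341), coding gene bodies in CG (0.0323) and CHG (0.0127), pseudogenes in CG (0.126), arms in CHH (0.0197), flanks in CHH (0.0215), CAG and CTG (0.0452) and other CHH (0.0173). Corrected for the chloroplast background, coding gene bodies in CHH read -0.0198. Leaving out each library gave ranges of -0.554 to 0.116 for genome-wide CHG and -0.198 to 0.112 for CHH, the upper ends without control replicate 1, as throughout. In CG the pseudogene range was -1.43 to 0.0669. In CHG the ranges were -0.911 to 0.788 in pericentromeres, -0.0844 to 0.0279 in coding gene bodies, -0.397 to 0.0651 in flanks and -0.616 to 1.43 in pseudogenes. In CHH they were -0.449 to 0.255 in pericentromeres, -0.0861 to 0.0726 in arms, -0.0218 to 0.0523 in coding gene bodies, -0.137 to 0.140 in flanks and -0.598 to 0.363 in pseudogenes. By trinucleotide they were -0.394 to 0.176 for CAA and CTA, -0.765 to 0.000642 for CCG, -0.501 to 0.148 for CAG and CTG, and -0.0947 to 0.0974 for other CHH. At the read totals and with the 3 replicates per group of these data, a CHG window difference of 20 points was recovered in 43 of 100 simulated cases. These were scored at an adjusted p below 0.05 without the minimum difference, and how much of this depth alone sets was not tested.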

Other observations

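Without control replicate 1, 36 gene bodies were called higher in Dox in CHG, beside the larger number of CHH windows given above for that setting. They were 35 pseudogenes and 1 coding gene (AT3G05410), and 24 lay in pericentromeres. Their median CHG level was 38.5% in the 2 remaining control libraries and 44.1% in the 3 Dox libraries, with differences from 3.90 to 13.2 points. In control replicate 1 itself the median was 45.3%, and it lay at or above the Dox mean in 26 of the 36. This comparison leaves 2 control libraries, and the genes were not called with all 3.

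The tests below, except the thinning to equal depth, were chosen or written down after their results were seen. The libraries have a structure that does not follow the labels. The split that puts control replicate 1 with Dox replicates 1 and 2 called 1006 gene bodies in CHG, where the labelled split called 0, and it was alone the highest in all 5 counts of calls in which any split called more than 1. This split was picked for its CHG gene bodies, which are 1 of the 5 counts. The other counts come from the same libraries, so the 5 are not separate support. Sequencing depth does not account for the calls of this split: with every library thinned to the depth of the shallowest, 855 gene bodies were called, 774 of them among the 1006. Incomplete conversion does not either: the genes called differed by a median of 4.06 CHG points, against a whole range of 0.0784 points in the chloroplast background. An exchange of a control and a Dox library may account for it, and so may an unlabelled difference in leaf material or handling; they cannot be told apart, because the chloroplast depth relative to nuclear depth parts the libraries the same way (156.9, 158.1 and 160.2 against 189.6, 213.3 and 213.7), and a treatment effect stays open too.

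Of the 160 CHH windows called between the labelled groups, 1 had a depth per cytosine of at least 1.5 times the median of tested windows, against 1.34% of tested windows, which argues against repeats collapsed in the reference as their cause. Reads misplaced between similar copies were not tested. Of the 10 splits of the 6 libraries, 6 called at least as many CHH windows as the labelled split, and the highest other split called 1724. In CHG windows 5 of the 10 splits called at least the 3 of the labelled split (highest other 43), and in CG windows all 10 called at least its 0 (highest other 1). For gene bodies the labelled split called 0 and the highest other split 0 in CG, 1006 in CHG and 190 in CHH, so that all 10 splits called as many; for flanks the highest others were 0, 46 and 0. With 10 splits no share under 0.05 can be reached. The splits with several times the real count point to a structure of the samples.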
